A study of Bacillus subtilis with 6 samples.

How the data were processed

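The sample records, each its own group, were the transcripts and OPP signal of the main late transition experiment, and 4 late log libraries with and without OPP at 2 and 20 minutes. Per the labels, cells were fixed, permeabilised with lysozyme, hybridised with DNA probes and run on a 10x Chromium controller. For OPP samples an oligonucleotide was attached by click chemistry. Cell Ranger 7.1 is named in the submitters' processing notes; the probe reference and genome build are not given in the sources used here. The labels do not state how long the main culture was exposed to OPP. The labels name v2 chemistry.

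The deposited values are raw UMI counts per probe and barcode, as sparse matrices. The authors' matrices list 29765 gene probes and, in the main library, OPP and 16S features; the late log matrices list no OPP feature. Probes were summed to 2959 genes by the gene name in the probe name (median 11 probes per gene), and 2386 of these names matched symbols of the RefSeq assembly ASM904v1, which was used only for names and neighbouring genes. No coordinates are printed. Control features stayed out of all gene totals: 16S features had 1 UMI in the main library.

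The filtered main matrix was compared with the raw one entry by entry. Its barcodes all had at least 134 gene UMIs, so the minimum of 50 gene UMIs per cell removed none. Doublets were sought with Scrublet, which marked 3 of 40457 cells (0.00742%). It was not taken to have worked, and no doublets were removed. Late log barcodes were called as cells from a total of at least 10% of the 99th percentile of the top 10000 barcodes, which gave 24744, 19097, 23569 and 27723 barcodes (no OPP and OPP at 2 minutes, no OPP and OPP at 20 minutes) with minima of 4, 8, 3 and 7 UMIs. A count of 3 UMIs, used in place of 0, equals 13.7, 8.79, 20.6 and 6.64 CPM in these libraries.

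Counts were summed over cells and scaled to CPM, computed from the deposited counts. Ratios have exact 95% conditional binomial intervals. Genes needed at least 50 UMIs over both sides. A list was described by its median log2 ratio, by the percentile of that median among 10000 random lists matched on expression in 20 bins, and by a 95% interval from 200 Poisson redraws. Random members were drawn gene by gene, so the percentile does not allow for genes that vary together, as in an operon. OPP-high and OPP-low cells were the top and bottom 25% by OPP UMIs within each of 10 depth deciles. Cells were clustered with scanpy 1.11.5 on the top 500 variable genes among those in at least 1% of cells, 20 principal components, 15 neighbours and Leiden (leidenalg 0.10.2) at resolution 1, without the OPP feature. Cells are not replicates, so no p-value was made from them.

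The 4 late log libraries were tested with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood with terms for duration and OPP, filterByExpr, TMM and Benjamini-Hochberg adjustment at 0.05. Such p-values measure the spread between these libraries, including any difference of the OPP effect between durations. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used otherwise.

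Methods were tested on simulated data. For the ratios, 200 genes were changed 2-fold, and the intervals held the true ratio for 95.6% of 1439 genes in the 2-minute, 95.8% of 1562 genes in the 20-minute and 95.4% of 2848 genes in the OPP-high comparison. These counts were drawn with Poisson error only, as the intervals assume, so the coverage does not extend to spread between cells or libraries. For edgeR over both durations with 2428 genes tested, 2 of 94 genes changed 2-fold and 56 of 96 changed 4-fold were called in the right direction, with 3 calls among unchanged genes. The simulated dispersion was 0.1, and each changed gene had the same fold at both durations. This recovery does not extend to effects that differ between durations.

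Groups, gene lists, the tests of the comparisons and the rule for named genes were fixed before the data were examined, but not the tests of explanations for patterns found in the data. Named genes were the 12 highest and 12 lowest (OPP-high against OPP-low) or the 8 highest and 8 lowest (each duration) by the interval bound nearest 1, up to 10 genes per direction from edgeR, and up to 4 members per list, the 2 highest and the 2 lowest ratios. Other genes named in lists or for comparison with another setting were chosen after their values were seen. Alternatives covered cell minima, ranking without deciles, OPP per transcript UMI, the top and bottom 10%, removal of each gene's most counted probe, median centring, TMM, gene minima, random parts of the cells, barcode calling, DESeq2 1.42.0, size factors, filters, dropped terms and left-out libraries. Lists of the SigW, HrcA and CtsR regulons were added after seeing the data.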

Results

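The study measured translation and the transcriptome in the same single cells of Bacillus subtilis 168, a laboratory strain of a soil bacterium that makes spores. O-propargyl-puromycin (OPP) is a puromycin analogue that enters growing peptide chains, and an oligonucleotide attached to it by click chemistry was read as UMIs of an OPP feature beside DNA probes against 2959 genes. The main experiment came from late transition phase and had 2 sample records, transcripts and OPP signal. Their matrices held the same counts: all 40457 barcodes of the smaller one were among the 833551 of the larger one, and 0 of 7233235 shared entries differed, so both records were counted as 1 library. In that library 14900782 gene UMIs and 1523390 OPP UMIs were counted, with 9871953 gene UMIs on the 40457 filtered barcodes, called cells below. The other 4 libraries came from late log phase and had no OPP feature: no OPP and OPP, each at 2 and at 20 minutes. They were shallow, with 302289 gene UMIs without and 507344 with OPP at 2 minutes, and 198524 without and 599905 with OPP at 20 minutes. Barcodes called as cells had medians of 7, 14, 5 and 13 gene UMIs in that order. Each condition had 1 library, so no difference between libraries has a replicate check, and all intervals cover counting error only.

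The distribution of the OPP signal over cells was described first; the share of it that is background was not measured. Cells of the late transition library carried a median of 15 OPP UMIs (quartiles 7 and 31), and the mean was 27.1 (SD 45.7 over cells). The highest cell had 2926 OPP UMIs, and 740 cells (1.83%) had none. OPP signal went with transcript depth: the median was 8 in the lowest depth decile, where cells had a mean of 137 gene UMIs, and 44 in the highest, with a mean of 649. Spearman's rho between OPP UMIs and gene UMIs over the 40457 cells was 0.49, as a description of 1 library. In the 16388 cells with at least 200 gene UMIs the median was 27 OPP UMIs and rho 0.32. Barcodes just below the filter carried nearly as much OPP as those just above it. The median was 7 at 100 to 133 gene UMIs and 8 at 134 to 149 (some of them, at 134, outside the filtered barcodes). This was 9.08 and 9.40 OPP UMIs per 100 gene UMIs. These counts therefore do not separate translation from OPP signal that is not tied to a cell.

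**Figure D1:**
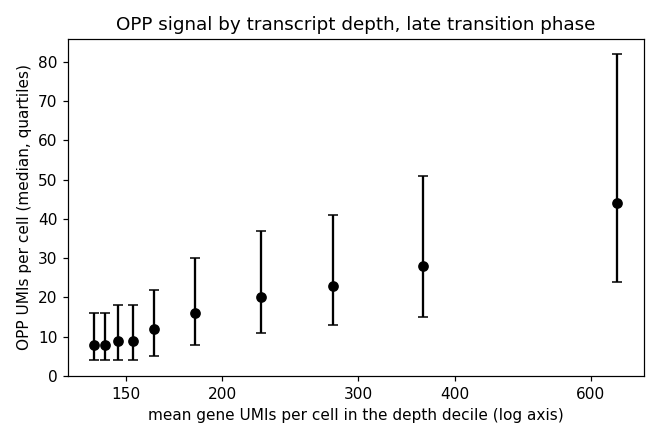
OPP UMIs per cell (points, median; bars, quartiles) against the mean gene UMIs per cell, on a log axis, for the 10 depth deciles of the late transition library. The median OPP signal goes from 8 to 44 UMIs between the lowest and the highest decile.

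OPP-high and OPP-low cells were compared to find transcripts that go with OPP signal. Within each depth decile the top and bottom 25% of cells by OPP UMIs were taken, 10110 cells per side, with means of 65.5 and 5.26 OPP UMIs. The OPP-high side stayed somewhat deeper, with means of 256 and 236 gene UMIs. Genes of fermentation and overflow metabolism, of cytochrome bd and of protein folding were higher in OPP-high cells. The acetoin genes alsD (acetolactate decarboxylase) and alsS (acetolactate synthase) had ratios of 1.66 (95% interval 1.57 to 1.75) and 1.62 (1.47 to 1.78), and ldh, lactate dehydrogenase, 1.55 (1.48 to 1.63). For cydA, cydC and cydD, which encode cytochrome bd oxidase and the transporter needed for its assembly, the ratios were 1.70 (1.46 to 1.97), 1.95 (1.64 to 2.33) and 1.81 (1.51 to 2.17). The chaperonin gene groEL was at 3553 CPM in OPP-high and 2290 CPM in OPP-low cells, a ratio of 1.55 (1.5 to 1.6). The transition state regulator abrB had a ratio of 1.79 (1.65 to 1.94), and yrkA 1.77 (1.66 to 1.90). The remaining genes with the highest lower bounds were yvaM (2.92, 1.49 to 6.13), zosA (1.92, 1.47 to 2.52) and yerA (1.68, 1.46 to 1.93).

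By list, 15 of 16 measured chaperone and Clp protease genes had a ratio above 1 and 2 of them reached 1.5, groEL and grpE (1.54, 1.43 to 1.67), while htpG was at 0.89 (0.83 to 0.97). The median log2 ratio of the list was 0.31, at percentile 100 of 10000 expression-matched random lists. Such percentiles count genes of the same operon as separate members, so they can overstate how far a list stands apart. The terminal oxidase list (11 of 12 above 1, median 0.43) and the overflow metabolism list (4 of 7 above 1, median 0.45) were at the same percentile, although pta and ackA of the acetate branch had ratios of 0.99 (0.91 to 1.06) and 0.95 (0.86 to 1.06). All 9 ATP synthase genes were above 1 (median 0.22, percentile 99.9), led by atpH at 1.31 (1.16 to 1.49). All 9 arginine biosynthesis genes were above 1 as well (median 0.25, percentile 99.9), with argJ at 1.32 (1.24 to 1.40) and argF at 1.01 (0.90 to 1.13). Ribosomal protein genes lay near a ratio of 1: 29 of 53 were above and 24 below it, 0 reached 1.5 in either direction, and the median log2 ratio was 0.00 (counting interval -0.00 to 0.02), with rpsT at 1.10 (1.06 to 1.14).

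Lower in OPP-high cells were transcripts of motility, nucleotide synthesis and secondary metabolism. Of the 16 motility genes 15 had ratios below 1 (median log2 ratio -0.17, percentile 0.03), such as the filament cap gene fliD at 0.85 (0.82 to 0.88). Of the 14 purine biosynthesis genes 12 were below 1 (median -0.20, percentile 0), among them purC at 0.83 (0.76 to 0.91). For pyrimidine biosynthesis 9 of 10 were below 1 (median -0.18, percentile 0.49), with pyrB at 0.77 (0.65 to 0.91) and pyrR at 1.17 (1.08 to 1.27). All 5 surfactin genes were below 1 (median -0.23, percentile 0.04), srfAA at 0.84 (0.80 to 0.87). The lists of branched-chain amino acid biosynthesis (9 of 11 below 1, median -0.15), sulfur and methionine (9 of 14, median -0.17) and bacillaene (14 of 15, median -0.16) were below percentile 1. The single genes with the lowest upper bounds were mostly rare transcripts: yxdJ at 0.51 (0.37 to 0.71), citA 0.58 (0.46 to 0.73), spsF 0.53 (0.37 to 0.74), oxdD 0.58 (0.44 to 0.76), abnA 0.55 (0.39 to 0.77), yhfW 0.57 (0.42 to 0.77), msmR 0.54 (0.37 to 0.78), yqbS 0.54 (0.36 to 0.79), ssuA 0.56 (0.40 to 0.79), proI 0.57 (0.41 to 0.80) and mdr 0.66 (0.54 to 0.82). The flagellar gene fliZ, with 570 UMIs in OPP-high and 749 in OPP-low cells, was at 0.70 (0.63 to 0.78).

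The size of these ratios moved with the depth of the cells. In the 16388 cells with at least 200 gene UMIs the chaperone median was 0.52, the overflow metabolism median 0.65 and the terminal oxidase median 0.58, and abrB reached 2.41 (2.17 to 2.68), alsD 2.18 (2.02 to 2.34) and groEL 1.91 (1.83 to 2.00). In the 24069 cells below 200 gene UMIs, a set chosen after seeing the data, the chaperone median was 0.02, the overflow metabolism median 0.05 and the motility median -0.02. There the arginine list had the opposite sign (-0.05), as did cydC with a ratio of 0.98.

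**Figure D2:**
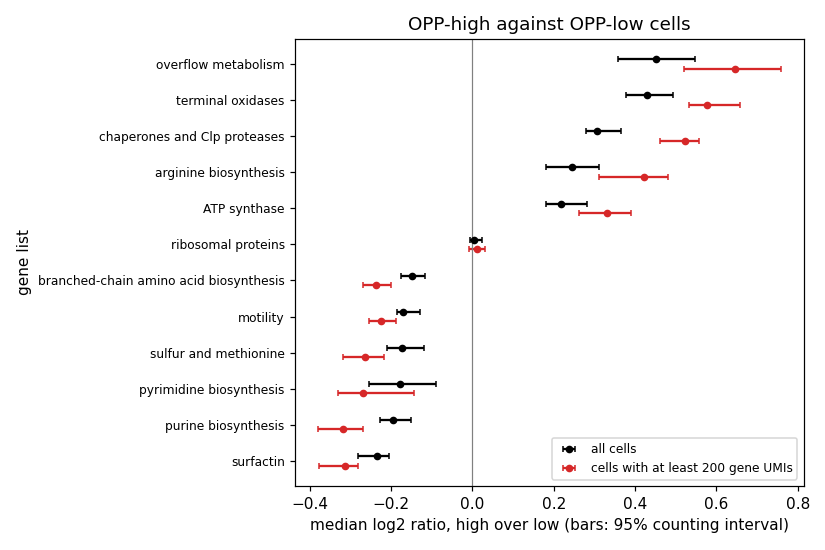
Median log2 ratio of OPP-high over OPP-low cells for 12 gene lists (bars, 95% counting interval), in all cells and in cells with at least 200 gene UMIs. Chaperones lie at 0.31 and 0.52, ribosomal proteins at 0.00 and 0.01, and purine biosynthesis at -0.20 and -0.32.

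Clustering on transcripts asks whether OPP signal differs between expression states. Among the 16388 cells with at least 200 gene UMIs, cluster 5 of 7 (2169 cells, 13.2%), defined by alsD, alsS, ldh, lctP and the cyd genes, had the highest OPP signal, with a median of 49 UMIs. Relative to cells of the same depth decile its mean was 1.60 (1.54 to 1.67 over resampled cells). Cluster 4 (2513 cells), defined by purine and pyrimidine genes such as purH and pyrE, had the lowest mean relative to depth, 0.82 (0.80 to 0.85), with a median of 25 UMIs, while the shallower cluster 1 had the lowest median, 22 UMIs, and a relative mean of 0.87. Over all 40457 cells the 6 clusters of at least 100 cells differed less: cluster 5 of that clustering, defined by ldh, alsS and alsD together with ytxH, nhaX and gspA and by no cyd gene, was at 1.13 (1.10 to 1.16) and the lowest at 0.94, while the 2 smaller clusters, of 87 and 40 cells, were at 0.75 (0.56 to 0.99) and 0.78 (0.57 to 0.95). The clustering of all cells was not stable. Without the 3 cells marked by Scrublet, its highest cluster was defined by alsS, alsD and cydA, cydB, cydC and cydD. That cluster was at 1.27 (1.22 to 1.32). No cluster had enough markers of 1 fixed cell type to be named. OPP-high and OPP-low cells were also compared within the 6 clusters of at least 1000 cells with at least 200 gene UMIs, a comparison chosen after seeing the data, and not every list kept its direction. The motility median was -0.52 in cluster 5, -0.11 in cluster 3 and -0.04 in cluster 2, but 0.07, 0.04 and 0.10 in clusters 1, 4 and 6, with counting intervals that held 0 in the last 4. The overflow metabolism median was -0.15 (-0.37 to -0.01) in cluster 5, 0.0066 and 0.038 in clusters 2 and 4, and 0.17 to 0.38 in the other 3. For ribosomal proteins the median was 0.15 (0.08 to 0.17) in cluster 5 and 0.08 (0.04 to 0.12) in cluster 1. In clusters 2, 3, 4 and 6 it lay between -0.02 and 0.04. The arginine median went from -0.14 to 0.31, while the chaperone and terminal oxidase medians were above 0 in all 6, with counting intervals that held 0 in cluster 2 for chaperones and in clusters 3 and 4 for terminal oxidases.

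**Figure D3:**
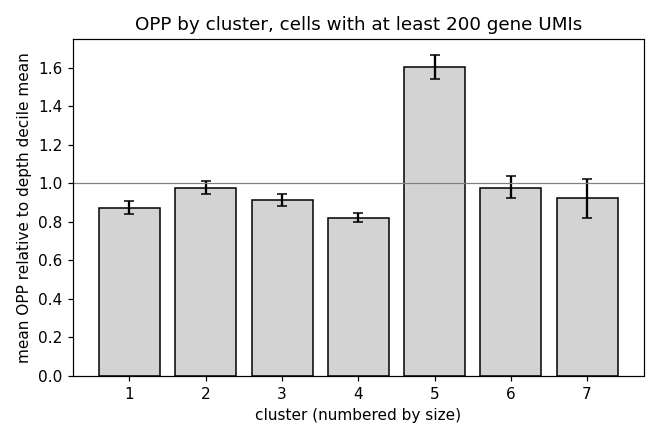
Mean OPP UMIs relative to the mean of the same depth decile (bars, with 95% range over resampled cells) for the 7 clusters of cells with at least 200 gene UMIs. Cluster 5 is at 1.60 and cluster 4 at 0.82.

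After 2 minutes in late log phase, OPP was compared with no OPP to see what the label itself does to the transcriptome. Sporulation and surfactin genes were lower with OPP, and motility and ribosomal protein genes higher. All 14 measured sporulation genes had ratios below 1 (median log2 ratio -1.23, percentile 0 of the random lists) and 13 were below by at least 1.5-fold. The forespore channel gene spoIIQ was at 199 CPM with and 1423 CPM without OPP, a ratio of 0.14 (0.11 to 0.18), spoVID at 0.23 (0.16 to 0.34), spoIIIAH at 0.29 (0.21 to 0.38) and spoIIE at 0.32 (0.27 to 0.39). Outside the list, gerQ was at 0.19 (0.10 to 0.34), prkA at 0.26 (0.17 to 0.38) and the oxalate decarboxylase gene oxdC at 0.31 (0.24 to 0.38). All 5 surfactin genes were lower (median -0.92, percentile 0), srfAA at 0.36 (0.34 to 0.38). Of 16 motility genes 15 were above 1 (median 0.84, percentile 100), including lytA, a lipoprotein gene of the autolysin operon lytABC, at 3.90 (2.67 to 5.86), the anti-sigma factor gene flgM at 2.80 (2.12 to 3.75) and cheV at 2.48 (2.00 to 3.10). Ribosomal protein genes were above 1 in 40 of 47 cases (median 0.52, percentile 100), with rpsJ at 3.04 (2.28 to 4.10). Other genes with high lower bounds were swrAA/1 (4.00, 2.64 to 6.32), yoaH (3.28, 2.32 to 4.75), the autolysin inhibitor gene iseA (2.73, 2.43 to 3.08) and yvcA (2.54, 2.07 to 3.14). The chaperone list did not stand apart (7 of 15 above 1, median -0.00, percentile 26.7), and groEL was at 1.00 (0.87 to 1.14).

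After 20 minutes the libraries differed far more. The SD of the log2 ratios over 1618 genes was 1.16, against 0.57 over 1472 genes at 2 minutes. Between the no-OPP libraries of 20 and 2 minutes it was 0.52 over 1229 genes, nearly as large as for OPP at 2 minutes. Chaperone and Clp protease genes were higher with OPP (13 of 16 above 1, median log2 ratio 2.28, percentile 100): hrcA, the repressor of the class I heat shock genes, at 12.03 (8.65 to 17.3), groES at 8.82 (4.72 to 18.6), mcsA at 8.02 (6.50 to 10.0), dnaK at 7.69 (6.22 to 9.62) and groEL at 6.40 (5.59 to 7.36). In the same list htpG was at 0.50 (0.35 to 0.73). Of 20 genes of the general stress sigma factor SigB 19 were at least 1.5-fold higher (median 2.00, percentile 100), with ohrB at 7.40 (5.83 to 9.52) and rsbW at 6.66 (5.49 to 8.14). The fosfomycin resistance gene fosB was at 11.6 (6.23 to 24.4) and ywsB at 6.87 (5.58 to 8.57). Ribosomal protein genes were above 1 in 50 of 51 cases (median 1.46, percentile 100), rplO at 6.36 (4.38 to 9.58).

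Among the gene lists, surfactin had the lowest median at 20 minutes (5 of 5 below 1, median log2 ratio -5.28, percentile 0). The synthetase genes srfAA, srfAB, srfAC and srfAD were at 0.041 (0.035 to 0.047), 0.024 (0.019 to 0.030), 0.024 (0.020 to 0.028) and 0.034 (0.027 to 0.044), and comS, the competence gene inside that operon, at 0.026 (0.010 to 0.055). Lower still was the sucrose antiterminator gene sacT, outside the lists, at 0.012 (0.0052 to 0.022). All 17 sporulation genes were below 1 (median -2.45, percentile 0), with spoIIE at 0.056 (0.041 to 0.076), and spoIIB outside the list at 0.058 (0.035 to 0.093). All 10 branched-chain amino acid biosynthesis genes were lower (median -2.85, percentile 0), ilvB at 0.064 (0.037 to 0.10) and leuC at 0.092 (0.064 to 0.13). Bacillaene genes (12 of 13 below 1, median -1.63), cannibalism toxin genes (9 of 10, median -0.81), aminoacyl-tRNA synthetase genes (18 of 18, median -0.84) and fatty acid biosynthesis genes (12 of 13, median -0.82) were below percentile 2. The median log2 ratio of all compared genes was -0.28, and TMM factors moved it to 0.19, so that ratios near 1 have no firm direction at 20 minutes. The no-OPP libraries also differed from each other: at 20 against 2 minutes without OPP, sporulation genes had a median of 0.82, SigB genes of 1.00, motility genes of -0.53 (13 of 15 below 1), cannibalism toxin genes of -0.42 and bacillaene genes of -0.34, all outside 95% of random lists. With the other no-OPP library as control, a choice made after seeing the data, the sporulation medians were -1.94 at 2 and -2.03 at 20 minutes.

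**Figure D4:**
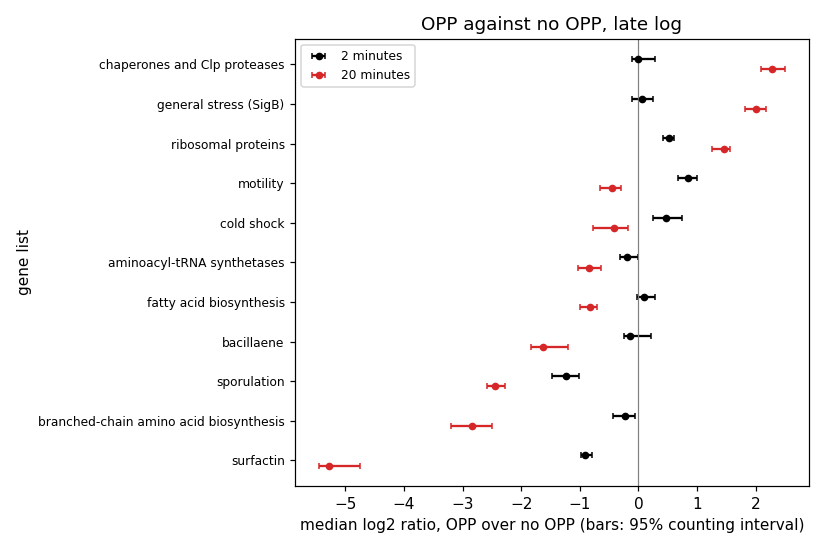
Median log2 ratio of OPP over no OPP in late log phase for 11 gene lists (bars, 95% counting interval) at 2 and at 20 minutes, with total-count scaling. Chaperones are at -0.00 and 2.28, surfactin at -0.92 and -5.28; the motility and cold shock medians at 20 minutes change sign with TMM factors.

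Over both durations, the OPP contrast was tested with the durations standing in as repeats. In edgeR's quasi-likelihood test with duration as a term and 1 residual degree of freedom, 0 of 2500 genes passed a Benjamini-Hochberg adjusted p of 0.05 (smallest 0.47). At an unadjusted p under 0.05 there were 233 genes, 87 higher and 146 lower. DESeq2 called 5 genes, iseA higher and sacT, spoIIE, spoIIQ and srfAA lower. Without the duration term edgeR called 0 genes on the 4 libraries (175 unadjusted). With that term dropped and 1 library left out as well, it called 405 genes without the OPP library of 2 minutes, 63 without that of 20 minutes, and 0 without either no-OPP library.

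The duration term of the same fit, 20 against 2 minutes over both OPP arms, also gave 0 genes of 2500 (smallest adjusted p 0.50) in edgeR and 0 in DESeq2, with 240 genes at an unadjusted p under 0.05 in edgeR, 182 higher and 58 lower. Without the OPP term edgeR called 0 genes on the 4 libraries (206 unadjusted). With that term dropped and 1 library left out as well, it called 342 genes without the no-OPP library of 20 minutes, 34 without the OPP library of 20 minutes, and 0 without either library of 2 minutes.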

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

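The tests on the spread of OPP UMIs in shallow barcodes, on chaperone transcripts within clusters and on the depth of the late log libraries, and the weighing of low depth by the top 200 genes beside hag, were chosen after the results they measure had been seen, and the patterns themselves were noticed in the data. Motility genes had a median log2 ratio of OPP over no OPP of 0.84 at 2 minutes and -0.45 at 20 minutes. Cold shock genes were at 0.47 and -0.41, and cell division genes at 0.18 and -0.26. These 3 lists stood out because both durations pointed in opposite directions, a difference that was not tested, and with TMM factors their 20-minute medians were 0.02, 0.06 and 0.21. OPP UMIs also lay outside the filtered barcodes of the late transition library, 428909 in all (28.2% of the total), of which 95.2% were on 40610 barcodes with at least 50 gene UMIs.

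In barcodes of the late transition library under 200 gene UMIs, OPP-high and OPP-low cells differed little in chaperone transcripts, with a median of 0.02. Over all compared genes the SD of the log2 ratios was 0.27 there, against 0.23 expected from counting. With at least 200 gene UMIs it was 0.34 against 0.20. The flagellin gene hag showed the same contrast: after thinning every barcode to 134 UMIs its variance over mean was 1.46 in the 24069 shallower barcodes and 2.06 in the 16388 deeper ones. The excess over 1 in the shallower barcodes was thus 0.434 of that in the deeper ones (0.399 to 0.476 over resampled barcodes), below the 0.8 set for low depth alone. That bound rested on hag, and over the top 200 genes the median variance over mean was 1.34 in the shallower and 1.31 in the deeper barcodes. For the spread between barcodes, low depth thus stays open. Few gene UMIs would widen ratios of summed UMIs but not move them to 1. Under 200 gene UMIs the HrcA, CtsR and SigW medians were 0.04 (-0.04 to 0.09), 0.00 (-0.06 to 0.07) and 0.07 (-0.00 to 0.12). From 200 they were 0.65 (0.59 to 0.71), 0.52 (0.46 to 0.57) and 0.59 (0.52 to 0.64). For the OPP contrast of these lists, the values argue against few gene UMIs alone. The lists and the cut at 200 were chosen after seeing the data, and HrcA and CtsR share genes with the chaperone list. Few OPP UMIs could also blur the ranking of the shallower barcodes, which was not tested. Their OPP-high and OPP-low sides had means of 39.4 and 2.53 OPP UMIs. Droplets holding free RNA in place of a cell may make up part of the shallower barcodes, but 0.434 lies between the values set for and against this. These values rested on hag as well, and over the top 200 genes the shallower barcodes were no less spread (1.34 against 1.31). The test thus does not decide on free RNA. The variance over mean of OPP UMIs was 37.1 in the shallower barcodes and 24.7 in barcodes with 1 to 9 gene UMIs. The latter had a mean of 0.012 OPP UMIs and a median of 0, so their variance over mean does not decide on free OPP oligonucleotide. Mean OPP UMIs were 10.7 from 100 to under 134 gene UMIs, 13.2 from 134 to under 150 and 18.7 from 150 to under 200. These means argue against free oligonucleotide spread evenly over all barcodes. Other OPP signal that is not tied to a cell stays open, and no biological explanation was tested.

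Chaperone transcripts were higher in OPP-high cells, with a median log2 ratio of 0.52 in cells with at least 200 gene UMIs. Depth is argued against as the cause, since the deepest against the shallowest 25% of these cells gave a chaperone median of 0.10, and so is a single cluster, since the median was above 0 within 6 of 6 clusters of at least 1000 cells (0.12 to 0.53; 5 with a counting interval above 0). A candidate explanation is a response of the cells to OPP itself, as in the 20-minute library: across 513 genes, which are not independent replicates, Spearman's rho between the log2 ratios of OPP-high cells and of OPP exposure for 20 minutes was 0.38 (0.32 to 0.46), and 0.31 without chaperone and SigW genes. This leaves other lists unexplained, because ribosomal protein genes were at 1.46 after 20 minutes and 0.01 in OPP-high cells, SigB genes at 2.00 and 0.05, and overflow metabolism genes at -0.77 and 0.65, and rho with the 2-minute ratios was 0.07. A tie between chaperone expression and translation before OPP was added stays open and untested, as the labelling time of the late transition culture is not given in the sources used here.

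SPbeta prophage genes were nearly absent from the late log libraries. The 22 genes of the list had 150 UMIs in the 4 libraries together, 0.0274 (0.0232 to 0.0322) of the 5470 that their share in the late transition library gives, which argues against low depth. Genes between the list members in the reference order, such as the sublancin gene sunA (0 UMIs in late log, 8907 in late transition phase), reached 0.0187 of their expected 6564 UMIs, while 20 genes on either side reached 0.848 and 1.19, although the yot genes and sspC among the former were also near 0. The whole locus may thus be absent or silent in the late log cultures, or its probes missing from that probe pool, and the values do not separate these. Growth phase and experiment differ together here.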

How the results depend on the processing

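Alternatives added only after seeing the data were the cells under 200 and with at least 300 gene UMIs, the settings that combine at least 200 gene UMIs with another choice, the no-OPP library of the other duration as control and the deeper late transition cells. Of 1953 alternatives for 217 results, 1442 stayed within the counting interval or within 1.5 times a count, 502 moved and 9 reversed, counting only values that lay outside 95% of random lists or had an interval without 1. Another 151 alternatives changed the sign of a value that did not stand apart in this way. Some alternatives for the late transition cells could not test a result. A minimum of 20 gene UMIs kept the same 40457 cells, so every value stayed. Removing Scrublet calls took out 3 cells, which could move little outside the clustering. For moved and reversed values the cause was not tested. The labels carry no replicate numbers to block on, and duration pairs the OPP and no-OPP libraries in the edgeR fit. Depth is 1 limit of the late log ratios, since 3 UMIs equal 20.6 CPM in the shallowest of these libraries.

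OPP signal per cell had a median of 27 UMIs with at least 200 gene UMIs and 10 below 200, with Spearman's rho of 0.322 and 0.195. The ratio of the highest to the lowest cluster of at least 100 cells was 1.17 at resolution 0.5, 1.95 with at least 200 gene UMIs and 1.35 with Scrublet calls removed, against 1.21. Removing those calls took out 3 of 40457 cells, so the last value shows how little it takes to change these clusters.

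In OPP-high against OPP-low cells, medians are given in the order motility, ribosomal proteins, chaperones, overflow metabolism, where they moved. Ranking over all cells gave -0.19, -0.0129, 0.18 and 0.19. The top and bottom 10% gave -0.32 for motility, 0.50 for chaperones and 0.57 for overflow metabolism, and OPP per transcript UMI -0.10 for motility. Cells with at least 200 gene UMIs gave -0.22 for motility, 0.52 for chaperones and 0.65 for overflow metabolism. Cells under 200 gave -0.0232, -0.0121, 0.0210 and 0.0520. At least 300 gene UMIs gave -0.29 for motility, 0.65 for chaperones and 0.87 for overflow metabolism. At least 200 gene UMIs ranked over all cells gave -0.30, 0.0356, 0.43 and 0.72. The same minimum without each gene's top probe gave -0.24 for motility, 0.52 for chaperones and 0.68 for overflow metabolism. With the 300 most counted genes left out of the totals it gave -0.20, 0.0369, 0.55 and 0.67. Median centring and TMM moved ribosomal proteins to 0.0423 and 0.0419. Reversed were the arginine list (-0.0463), cydC (0.976) and abnA (1.03) in cells under 200 gene UMIs, the nitrogen limitation list with the top and bottom 10% (-0.0369), and the cell wall list when ranked over all cells (-0.0122) and with the top and bottom 10% (-0.000395).

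At 2 minutes the sporulation median was -0.95 in the top 3000 barcodes, -0.92 for genes with at least 200 UMIs and -1.94 against the other no-OPP library. Ribosomal proteins were at 0.62 with TMM and 0.39 against the other no-OPP library, and chaperones at 0.36 for genes with at least 200 UMIs. At 20 minutes the sporulation median was -2.17 with median centring, -1.98 with TMM and -2.03 against the other no-OPP library. Ribosomal proteins were at 1.61 without top probes, 1.74 with centring and 1.93 with TMM, and chaperones at 2.53 in the top 3000 barcodes, 2.57 with centring, 2.76 with TMM and 2.61 for genes with at least 200 UMIs. The matrix list reversed with all barcodes (-0.0457), and the phosphate limitation list with centring (0.16) and TMM (0.35). The motility, cold shock and cell division medians also changed sign with TMM (0.02, 0.06 and 0.21), and the cell division median with centring (0.02).

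In late transition against late log, sporulation was at -3.82 without top probes and -3.87 with centring, phosphate limitation at -6.55 and -6.57, and ribosomal proteins at 2.62 with centring. For OPP over both durations, DESeq2 called 5 genes where edgeR called 0 (233 at an unadjusted p under 0.05). Without the OPP library of 2 minutes edgeR called 405, without that of 20 minutes 63, and without either no-OPP library 0. For duration, where edgeR called 0 (240 unadjusted) and DESeq2 0, it called 342 without the no-OPP library of 20 minutes, 34 without the OPP library of 20 minutes and 0 without either library of 2 minutes. In these fits the second term was dropped and a lone library was assumed to vary like the other group.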

Other observations

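The SigW, HrcA and CtsR lists, the comparison of UMI shares with probe shares and the test of exchanged labels were chosen only after seeing the data. Late transition phase and late log phase differ here together with experiment, depth and OPP exposure, since the late transition library was labelled with OPP and the late log libraries compared had none, so the following values are descriptive. Ribosomal protein genes were higher in the late transition library than in both no-OPP late log libraries summed, with a median log2 ratio of 2.42 (52 of 53 above 1, percentile 100 of random lists), among them rpmC at 30.6 (95% interval 19.6 to 50.8). Purine biosynthesis genes were at 2.50 (14 of 14 above 1), with purL at 11.6 (8.88 to 15.4), pyrimidine biosynthesis genes at 1.94 (10 of 10) and arginine biosynthesis genes at 2.38 (9 of 9), with argJ at 8.34 (6.02 to 11.9). The general stress list was at 1.68 (20 of 21), with dps, a DNA-protecting ferritin-like protein, at 14.4 (12.8 to 16.2). SPbeta genes were at 3.82 (22 of 22), among them yokG at 73.7 (35.8 to 183). In the late log libraries compared, yolB, yosS and yonN had 0 UMIs, counted as 3. That floor set their ratios, so the SPbeta median is not an exact size.

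All 13 phosphate limitation genes were higher in the late log libraries (median -6.78, percentile 0): pstS, the phosphate-binding protein of the uptake system, had 29374 CPM in late log and 36.4 CPM in late transition phase, and the alkaline phosphatase gene phoB 17381 and 44.6 CPM. All 22 measured sporulation genes (median -4.08) had the same direction, with spoIVA at a ratio of 0.023 (0.021 to 0.026), as had 9 of 10 cannibalism toxin genes (median -3.48), with skfA at 0.010 (0.0091 to 0.012) and sdpA the exception at 1.40 (1.22 to 1.62), and all 5 surfactin genes (median -2.20). Fatty acid biosynthesis genes were at -1.09 (13 of 14 below 1). Phosphate limitation genes held 17.8 and 14.9 times their share of the probes in the no-OPP libraries of 2 and 20 minutes, and 0.144 times in the late transition library, so the late log level was not an even background over probes. Exchanged growth-phase labels were also considered, from the sporulation median of -4.08, which did not decide the question, since growth phase, experiment and OPP exposure differ together. With OPP in late log phase the sporulation medians were -1.23 at 2 and -2.45 at 20 minutes, and at 20 minutes the ribosomal protein (1.46), SigB (2.00), surfactin (-5.28), cannibalism toxin (-0.81) and fatty acid (-0.82) medians also had the sign found here, so part of these differences cannot be told apart from OPP exposure. Phosphate limitation genes were at -0.14 and -0.12. Other genes were higher in the late transition library, among them dps, yvyD, which encodes the ribosome hibernation factor (4.51, 4.06 to 5.02), and ldh (12.3, 9.13 to 17.1).

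Genes of SigW, the sigma factor of cell envelope stress, were higher with OPP at 20 minutes (28 of 33 above 1, median log2 ratio 1.38, percentile 100) and had a median of -0.17 at 2 minutes. In OPP-high cells 32 of 33 were above 1, with medians of 0.40 in all cells and 0.59 in cells with at least 200 gene UMIs. In the 24069 cells below 200 the SigW median was 0.07 (24 of 33 above 1), and the HrcA and CtsR medians were 0.04 and 0.00. The HrcA list, the class I chaperone operons, was at 2.77 at 20 minutes, -0.00 at 2 minutes and 0.42 in OPP-high cells. The CtsR list, the Clp genes under the repressor CtsR, was at 2.28, -0.20 and 0.31. Both the HrcA and the CtsR list share genes with the chaperone and Clp protease list, so they repeat that result and add no separate evidence. The log2 ratios of OPP at 2 and at 20 minutes had a Spearman's rho of 0.44 across 424 genes.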
